A study of Mus musculus with 26 samples.

How the data were processed

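Messenger RNA was measured in 26 libraries of OVA-specific T cells, 12 from OT-I and 14 from OT-II cells, sorted from pools of 3 mice and made into polyA-primed SmartSeq cDNA in 2 experimental batches. The labels name the treatments, the batches and the replicate numbers. The series text speaks of pooled spleen, liver and lymph nodes, and the extraction protocol of spleens and lymph nodes. The groups per cell type were saline, OVA and pMan-OVA, with 3, 2 and 3 OT-I libraries in batch 1 and 1, 2 and 1 in batch 2, and with 3, 2 and 3 OT-II libraries in batch 1 and 2, 2 and 2 in batch 2.

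The deposited values are expected counts (estimated reads per gene, in whole numbers, not scaled for depth) that the authors made with bcl2fastq and kallisto 0.46.1 on GRCm38, per the submitters' processing notes. The transcript set, the step from transcripts to genes and the rounding are not stated. The tables hold 21900 protein-coding genes, of which 94 identifiers had no symbol in the reference annotation, from which positions were also taken. The libraries are not stranded, so antisense and overlapping transcripts are counted with the gene. No column was left unused (0). Library totals were 26058858 to 68228283 in OT-I and 27488895 to 72457076 in OT-II cells. The 10 genes with the most counts took 4.92% to 6.94% of a library. No pair of libraries of one group and batch was a copy of the other, tested on genes with at least 20 counts.

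Counts were analysed in R 4.3.3 with edgeR 4.0.16. Per cell type, genes with low counts were removed by filterByExpr with the groups, TMM factors were computed, and a quasi-likelihood model with robust dispersions, group and batch as terms was fitted. Each pair of treatments was compared with its F test, two-sided, at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. Log2 fold changes are fitted values, and their SE is the size of the change divided by the square root of F. Levels of named genes are CPM, the counts scaled to library totals with TMM factors, as mean ± SD over libraries, each a separate pool within its group. Levels of lineage and marker genes in single libraries are CPM of plain library totals. The difference between the cell types was tested in one model of all 26 libraries with batch and batch by cell type as terms. Within-batch values are differences of mean log2 CPM with a prior count of 1. Calls in 2 comparisons that share saline libraries were set beside 20 simulations of unchanged groups with the same controls, and beside fits in which the saline libraries were split between the comparisons.

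A set of 35 gene lists with 618 members was fixed: 24 of T cell programmes, 2 of lineage and 9 of markers of other cells. The programme lists cover inhibitory receptors and exhaustion, anergy, cytotoxic effectors, naive and memory cells, activation, immediate early and stress genes, S phase, G2 and M phase, type I interferon, interferon gamma, T follicular helper, regulatory T, T helper 1, T helper 2 and 17, and regulatory type 1 cells, apoptosis, glycolysis, oxidative phosphorylation, cholesterol synthesis, chemokine receptors and homing, T cell receptor signalling, the unfolded protein response, ribosomal proteins and mitochondrially encoded genes. The lineage lists are of CD8 and CD4 T cells. The markers are of B cells, plasma cells, macrophages and monocytes, dendritic cells, NK cells, neutrophils, erythroid cells and platelets, hepatocytes, and stroma and endothelium. Some genes stand in more than one list. Lists with at least 3 measured members were tested with camera (limma 3.58.1) at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists and the 3 comparisons of a cell type. The members past the threshold were counted over all genes and adjusted over the list alone.

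Genes are named by a rule. Pdcd1, Lag3, Tox, Ctla4, Gzmb, Ifng, Il2ra, Tcf7, Il7r and Mki67 are named in each comparison, and in OT-II cells also Foxp3, Cxcr5, Bcl6, Il21 and Tbx21. Further named are the 6 genes with the largest rise and the 6 with the largest fall among those that passed, with a mean log2 CPM of at least 3 and the same direction in both batches, without genes known by a model name. For the difference between cell types the numbers are 5 and 5. From each list with at least 3 members past the threshold or a camera call, up to 4 members that passed are examples; a few of them are not reported here. Aqp9, named as the last of 6 called genes, and the differences between cell types for Tox and Izumo1r, were chosen after their values were seen.

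The comparisons, models, lists, rule and most alternatives were chosen before the data were examined. The alternatives were median-of-ratios (RLE) size factors, no filter, a log2 fold change of at least 1, DESeq2 1.42.0, limma voom with sample quality weights, no batch term, each batch alone, all libraries in one fit, the replicate number as a block, fry in place of camera, and leaving out each library in turn. Chosen after seeing the data were fits without 4 libraries whose median B cell marker level was above 5 log2 CPM, fits with this level as a covariate, and counts of each library thinned at random to 26058858. The fit without OT-II pMan-OVA b1r2, also chosen then, is one of those that leave out a library.

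The model was tested on simulated data with these group sizes and spreads. Of genes changed 4-fold, 63.6% to 79.7% were called in the 6 comparisons within a cell type and 56.9% to 67.2% in the tests between cell types. For a 2-fold change these shares were 39.7% to 70.1% and 24.6% to 34.8%, and for a 1.5-fold change 7.69% to 34.8% and 6.25% to 10.8%. Of the calls, 1.02% to 8.26% were of unchanged genes and 0 had the wrong sign. Of 20 unchanged lists 0 were called, but lists of correlated genes were not tested.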

Results

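The study measured messenger RNA in T cells specific for ovalbumin (OVA) after mice received OVA, a synthetically mannosylated form of OVA (pMan-OVA) or saline. OT-I cells are CD8 T cells and OT-II cells are CD4 T cells, each with a transgenic receptor for an OVA peptide. Per the labels, 750000 cells were transferred into C57BL/6 mice on day 0, the treatment was injected intravenously on day 1, and cells were sorted 4 days later from pools of 3 mice. The mannosylated form was given at 5 µg, and free OVA at the molar equivalent. There were 26 libraries, each from one such pool, in 2 experimental batches. OT-I cells gave 4 saline, 4 OVA and 4 pMan-OVA libraries, and OT-II cells gave 5, 4 and 5. Library totals ran from 26058858 to 72457076 estimated counts, and 14074 to 16199 genes were detected per library. Libraries are named below by group, batch and replicate number, b1r2 being replicate 2 of batch 1.

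Lineage genes followed the labels in 26 of 26 libraries. Cd8b1, a chain of the CD8 coreceptor, lay between 1780 and 2270 CPM (counts scaled to the library total) in OT-I libraries and between 25.1 and 207 in OT-II libraries. Cd4 lay between 0.326 and 7.11 CPM in OT-I libraries and between 248 and 916 in OT-II libraries. The OT-II OVA library b2r2 stood apart from the other OT-II libraries. It held the B cell genes Cd79a at 1390 CPM (14.9 to 168 in the others) and Ms4a1 at 1270 (5.7 to 134), and the myeloid gene Lyz2 at 1070 (23.5 to 269). In the same library Cd3e, a subunit of the T cell receptor complex, lay at 383 CPM (905 to 1250 in the others). The median level of 15 B cell markers was 9.22 log2 CPM there, and it was also above 5 in 3 other libraries of batch 2: OT-II saline b2r1 (6.1), OT-II pMan-OVA b2r1 (6) and OT-I OVA b2r2 (5.4).

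**Figure D1:**
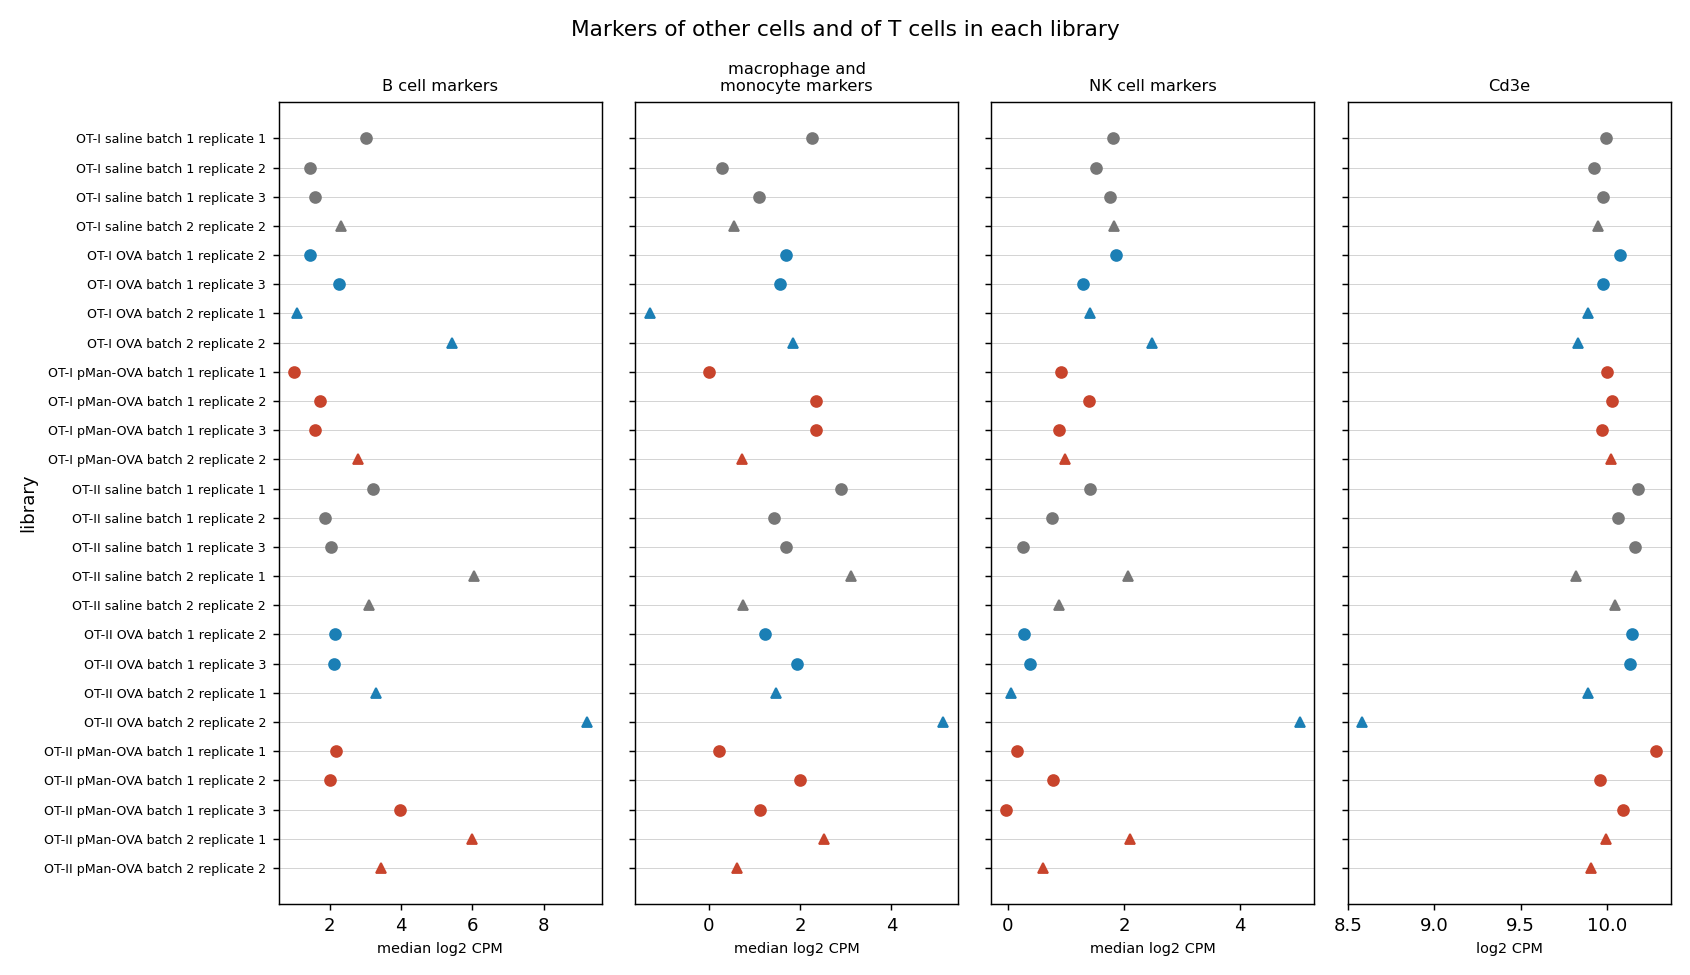
Levels of marker genes of other cells and of Cd3e in each of the 26 libraries, as the median log2 CPM of B cell, macrophage and monocyte, and NK cell markers and as log2 CPM of Cd3e; circles are batch 1 and triangles batch 2. OT-II OVA b2r2 lies at 9.22 for B cell markers.

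OT-I cells given free OVA were compared with OT-I cells given saline to ask what the antigen alone does to CD8 T cells. Pdcd1, Itgb1 and Nrp1 were among the genes that rose, and Il7r was among those that fell. Pdcd1 (ENSMUSG00000026285, chromosome 1, 94038305 to 94052553, minus strand, GRCm38), which encodes the inhibitory receptor PD-1, went from 3.99 ± 0.73 CPM (SD, n = 4) to 31.9 ± 7.19 (SD, n = 4), a log2 fold change of 2.92 ± 0.18 (SE; edgeR adjusted p = 4.95e-07). Itgb1 (ENSMUSG00000025809, chromosome 8, 128685654 to 128733200, plus strand), the integrin beta 1 chain through which cells bind extracellular matrix, went from 125 ± 24 to 1160 ± 224 CPM (SD, n = 4 each; log2 fold change 3.20 ± 0.17, adjusted p = 1.9e-07). Nrp1 (ENSMUSG00000025810, chromosome 8, 128358604 to 128503363, plus strand), a semaphorin coreceptor, went from 3.62 ± 1.24 to 51.4 ± 17.4 CPM (SD, n = 4 each; 3.73 ± 0.24, adjusted p = 8.01e-07). Within batch 1 and batch 2 the differences were 2.82 and 3.06 for Pdcd1, 3.31 and 2.86 for Itgb1, and 3.69 and 3.45 for Nrp1.

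The genes with the largest rises by the naming rule also included Zbtb32, a transcriptional repressor (4.96 ± 0.39), Gzmk, a granzyme (4.52 ± 0.80), Itgax, an integrin alpha chain of myeloid and some activated lymphoid cells (3.68 ± 0.62). Osbpl3 (3.42 ± 0.28) and Bspry (3.30 ± 0.24) followed. The largest falls were those of Plaur, the urokinase receptor (-1.42 ± 0.23), Itgae, the integrin chain CD103 that binds E-cadherin (-1.28 ± 0.26), Igfbp4, which binds insulin-like growth factors (-1.27 ± 0.20). Rgmb (-1.26 ± 0.26), Abhd15 (-1.24 ± 0.19) and Fos, a subunit of the AP-1 transcription factor (-1.16 ± 0.30), fell too. Adjusted p lay between 1.85e-06 and 0.00976 for these genes except Fos (0.0332). Rgmb no longer passed without saline b2r2 (adjusted p = 0.0628). Fos no longer passed in 8 of the 12 fits that each leave out 1 library (adjusted p up to 0.106). It still passed without pMan-OVA b1r1, pMan-OVA b1r3, saline b2r2 or OVA b2r2.

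Of the 20 genes of inhibitory receptors and exhaustion, 8 rose with OVA, and 10 did when adjusted over the list alone (camera adjusted p = 9.09e-12, and adjusted p = 0.00525 with an estimated correlation). They included Lag3, a receptor for MHC class II that restrains T cells (3.83 ± 0.29), Ctla4, which competes with CD28 for its ligands (2.65 ± 0.29), Cd200 (1.59 ± 0.25) and Cd160 (0.98 ± 0.14). Tox, a regulator of the exhausted state, had a log2 fold change of 0.12 ± 0.10 (adjusted p = 0.578). Of 16 anergy genes, 6 rose, and 8 when adjusted over the list alone (camera adjusted p = 3.04e-13, and adjusted p = 0.0114 with an estimated correlation), among them Izumo1r, the folate receptor FR4 (2.40 ± 0.24). Of 11 measured genes of regulatory type 1 cells, 5 rose, and 7 rose and 1 fell when adjusted over the list alone (camera adjusted p = 3.04e-13, and adjusted p = 0.00428 with an estimated correlation). Itga2, an integrin chain, was one of them (2.39 ± 0.36).

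Of 22 cytotoxic effector genes, 12 rose, and 15 when adjusted over the list alone (camera adjusted p = 2.16e-16, but adjusted p = 0.0682 with an estimated correlation). Klrk1, the activating receptor NKG2D, rose by 3.13 ± 0.29, Gzmb, a granzyme, by 3.28 ± 0.50, Ifng, which encodes interferon gamma, by 2.22 ± 0.32 and Tbx21, the transcription factor T-bet, by 2.17 ± 0.19 on the log2 scale. Of 14 T helper 1 genes, 8 rose and 1 fell, and 9 rose and 1 fell when adjusted over the list alone (camera adjusted p = 3.35e-11, and adjusted p = 0.0088 with an estimated correlation). Cxcr3, a chemokine receptor of effector cells, rose by 2.07 ± 0.18. Of 20 activation and costimulation genes, 7 rose and 2 fell (9 and 3 when adjusted over the list alone; camera adjusted p = 0.00159, but adjusted p = 0.0682 with an estimated correlation). The adhesion receptor Cd44 rose by 1.72 ± 0.15 and the transcription factor Irf4 by 1.38 ± 0.19. Il2ra, the interleukin 2 receptor alpha chain, had a log2 fold change of -0.04 ± 0.55 (adjusted p = 0.984). The granzyme and killer-lectin receptor families hold near-identical members, between which the authors' counting could divide reads, so single members are less certain.

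Of 22 genes of G2 and M phase, 19 rose, and 21 when adjusted over the list alone (camera adjusted p = 1.05e-39, and adjusted p = 0.0482 with an estimated correlation). Mki67, a marker of cycling cells, went from 7.98 ± 4.88 to 53.3 ± 11.1 CPM (SD, n = 4 each; 2.69 ± 0.30, adjusted p = 7.06e-05), and the mitotic cyclin Ccnb1 rose by 2.56 ± 0.21. Of 22 S phase genes, 9 rose, and 12 rose and 1 fell when adjusted over the list alone (camera adjusted p = 1.61e-06, but adjusted p = 0.414 with an estimated correlation). Tk1, a thymidine kinase, rose by 1.92 ± 0.28. Of 20 naive and memory genes, 6 fell, among them the interleukin 7 receptor Il7r (-0.63 ± 0.10) and the survival factor Bcl2 (-0.68 ± 0.11), and 2 rose, Slamf6 among them (1.06 ± 0.09). This list gave 3 higher and 8 lower when adjusted over the list alone (camera adjusted p = 0.0196, but adjusted p = 0.212 with an estimated correlation). Tcf7, a transcription factor of naive and memory cells, stayed at 0.01 ± 0.09 (adjusted p = 0.965). Of 20 immediate early and stress genes, 3 fell, Jun among them (-0.99 ± 0.18), and 9 fell when adjusted over the list alone (camera adjusted p = 1.46e-06, but adjusted p = 0.274 with an estimated correlation).

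Further lists had a camera call in this comparison. T follicular helper genes had 7 of 13 higher and 1 lower, over all genes and adjusted over the list alone (adjusted p = 1.59e-11, and adjusted p = 0.00462 with an estimated correlation). Cxcr5, a chemokine receptor that guides cells to B cell follicles, rose by 2.12 ± 0.14. Regulatory T cell genes had 4 higher and 1 lower of 14 (5 and 2 when adjusted over the list alone; 0.00036, but adjusted p = 0.118 with an estimated correlation). Apoptosis genes had 5 higher and 2 lower of 20 (9 and 3 when adjusted over the list alone; 1.85e-05, and adjusted p = 0.0109 with an estimated correlation). Chemokine receptor and homing genes had 6 higher and 3 lower of 20 (8 and 4; 8.12e-05, and adjusted p = 0.0167 with an estimated correlation). CD8 lineage genes had 3 higher of 8 (5 when adjusted over the list alone; 0.000767, but adjusted p = 0.126 with an estimated correlation).

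In all, 900 of 13724 genes passed, 680 higher and 220 lower with OVA; 2674 had an unadjusted p under 0.05, and DESeq2 called 1430, limma voom 1677 and one fit of all libraries 391. All 900 had the same direction in each batch. With batch 1 libraries alone 632 genes passed, and with batch 2 alone, where the saline group is 1 library, edgeR called 0, with 818 at an unadjusted p under 0.05. Of the 64 genes the naming rule took that passed, the 4 OVA and 4 saline libraries did not overlap in 59. Chance separates groups this size in 2.86% of genes no test chose. The named genes and all calls were chosen by one, so overlap and direction test nothing. Without OVA b1r2 the count was 481.

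OT-I cells given pMan-OVA were compared with saline to ask what the mannosylated antigen does to CD8 T cells. Pdcd1, Itgb1 and Nrp1 rose here too, and Ccr9 and Il7r fell. Pdcd1 reached 43.7 ± 4.84 CPM (SD, n = 4), a log2 fold change of 3.45 ± 0.18 over saline (edgeR adjusted p = 5.37e-08; 3.42 in batch 1 and 3.56 in batch 2). Itgb1 reached 1960 ± 211 CPM (SD, n = 4; 3.98 ± 0.17, adjusted p = 1.72e-08) and Nrp1 reached 84.2 ± 4.46 (SD, n = 4; 4.59 ± 0.25, adjusted p = 6.23e-08). Ccr9 (ENSMUSG00000029530, chromosome 9, 123678439 to 123784330, plus strand), a chemokine receptor that guides cells to the small intestine and thymus, fell from 121 ± 10.1 to 22.7 ± 3.02 CPM (SD, n = 4 each; -2.41 ± 0.16, adjusted p = 3.69e-07; -2.51 and -2.11 within the batches). Il7r fell from 405 ± 23.4 to 177 ± 18.7 CPM (SD, n = 4 each; -1.19 ± 0.10, adjusted p = 2.12e-06).

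By the naming rule the largest rises also included Zbtb32 (5.65 ± 0.41), Gzmk (4.71 ± 0.84), Itgax (4.23 ± 0.64) and S100a4, a calcium-binding protein of memory and effector cells (3.96 ± 0.40). The largest falls included Plaur (-2.84 ± 0.24), Igfbp4 (-2.58 ± 0.20), Itgae (-2.40 ± 0.26), Lrrc75b (-2.32 ± 0.22) and Ifngr2, a chain of the interferon gamma receptor (-2.31 ± 0.23). Adjusted p for these 9 genes lay between 1.05e-06 and 0.00304.

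Inhibitory receptor and exhaustion genes had 9 of 20 higher with pMan-OVA (11 when adjusted over the list alone; camera adjusted p = 4.56e-11, and adjusted p = 0.00525 with an estimated correlation). Lag3 rose by 4.83 ± 0.30, Ctla4 by 3.34 ± 0.29 and Eomes, a transcription factor of effector and memory cells, by 1.22 ± 0.16. Tox had a log2 fold change of 0.16 ± 0.09 (adjusted p = 0.3). Anergy genes had 8 of 16 higher (8 higher and 2 lower when adjusted over the list alone; camera adjusted p = 2.47e-12, and adjusted p = 0.0109 with an estimated correlation). Izumo1r rose by 2.84 ± 0.24. Regulatory type 1 genes had 6 higher and 1 lower of 11 (7 and 1 when adjusted over the list alone; camera adjusted p = 6.05e-10, and adjusted p = 0.00462 with an estimated correlation). Cytotoxic effector genes had 11 of 22 higher (13 higher and 1 lower when adjusted over the list alone; camera adjusted p = 3.7e-09, but adjusted p = 0.189 with an estimated correlation). Among them Ifng rose by 2.93 ± 0.32, Gzmb by 3.04 ± 0.51 and the chemokine Ccl5 by 2.63 ± 0.40. T helper 1 genes had 9 higher and 1 lower of 14 (9 and 2 when adjusted over the list alone; camera adjusted p = 4.96e-09, and adjusted p = 0.0114 with an estimated correlation). The member that fell was Cxcr6, a chemokine receptor of tissue-resident cells (-1.36 ± 0.13).

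Each of the 22 genes of G2 and M phase rose, over all genes and adjusted over the list alone (camera adjusted p = 2.45e-31, but adjusted p = 0.0682 with an estimated correlation). Mki67 rose by 2.98 ± 0.30 and Top2a, a DNA topoisomerase, by 2.13 ± 0.15. S phase genes had 9 higher and 2 lower of 22 (11 and 4 when adjusted over the list alone; camera adjusted p = 0.0323, but adjusted p = 0.82 with an estimated correlation). Naive and memory genes had 9 of 20 lower, Bcl2 among them (-1.26 ± 0.10), and 5 higher, Slamf6 among them (1.48 ± 0.09). When adjusted over the list alone, 11 and 5 passed (camera adjusted p = 0.00243, but adjusted p = 0.126 with an estimated correlation). Tcf7 had a log2 fold change of 0.17 ± 0.09 (adjusted p = 0.203). Immediate early and stress genes had 9 of 20 lower (12 when adjusted over the list alone; camera adjusted p = 2.96e-05, but adjusted p = 0.336 with an estimated correlation). Fos lay at -1.56 ± 0.29 and the chaperone gene Dnajb1 at -0.86 ± 0.15. T follicular helper genes had 8 higher and 1 lower of 13 (the same numbers adjusted over the list alone; camera adjusted p = 2.01e-11, and adjusted p = 0.00462 with an estimated correlation). Cxcr5 rose by 2.65 ± 0.14. Activation genes had 10 higher and 3 lower of 20, over all genes and adjusted over the list alone (camera adjusted p = 0.00384, but adjusted p = 0.0752 with an estimated correlation). Cd44 lay at 2.10 ± 0.15 and Cd40lg, the ligand of CD40, at -2.04 ± 0.21. Il2ra lay at -0.81 ± 0.51 (adjusted p = 0.32), and passed without saline b2r2 (-1.33, adjusted p = 0.0145).

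Among the further lists, apoptosis genes had 7 higher and 2 lower of 20 (8 and 2 when adjusted over the list alone; camera adjusted p = 0.000836, and adjusted p = 0.0291 with an estimated correlation). Regulatory T cell genes had 4 higher and 3 lower of 14, over all genes and adjusted over the list alone (camera adjusted p = 0.0339, but adjusted p = 0.336 with an estimated correlation). CD8 lineage genes had 4 of 8 higher (5 when adjusted over the list alone; camera adjusted p = 0.00508, but adjusted p = 0.189 with an estimated correlation). Chemokine receptor and homing genes moved both ways, 7 higher and 5 lower of 20 (the same adjusted over the list alone; median log2 fold change -0.10, mean 0.36, camera adjusted p = 0.123).

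In all, 2494 of 13724 genes passed, 1414 higher and 1080 lower with pMan-OVA; 4172 had an unadjusted p under 0.05, and 2468 of the 2494 differed in the same direction within both batches. One fit of all libraries called 1618. Batch 1 libraries alone gave 2572 genes, and batch 2 alone, with 1 library in each group compared, gave 2. The pMan-OVA and saline libraries did not overlap in 75 of the 82 named genes that passed (2.86% by chance for unchosen genes).

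**Figure D2:**
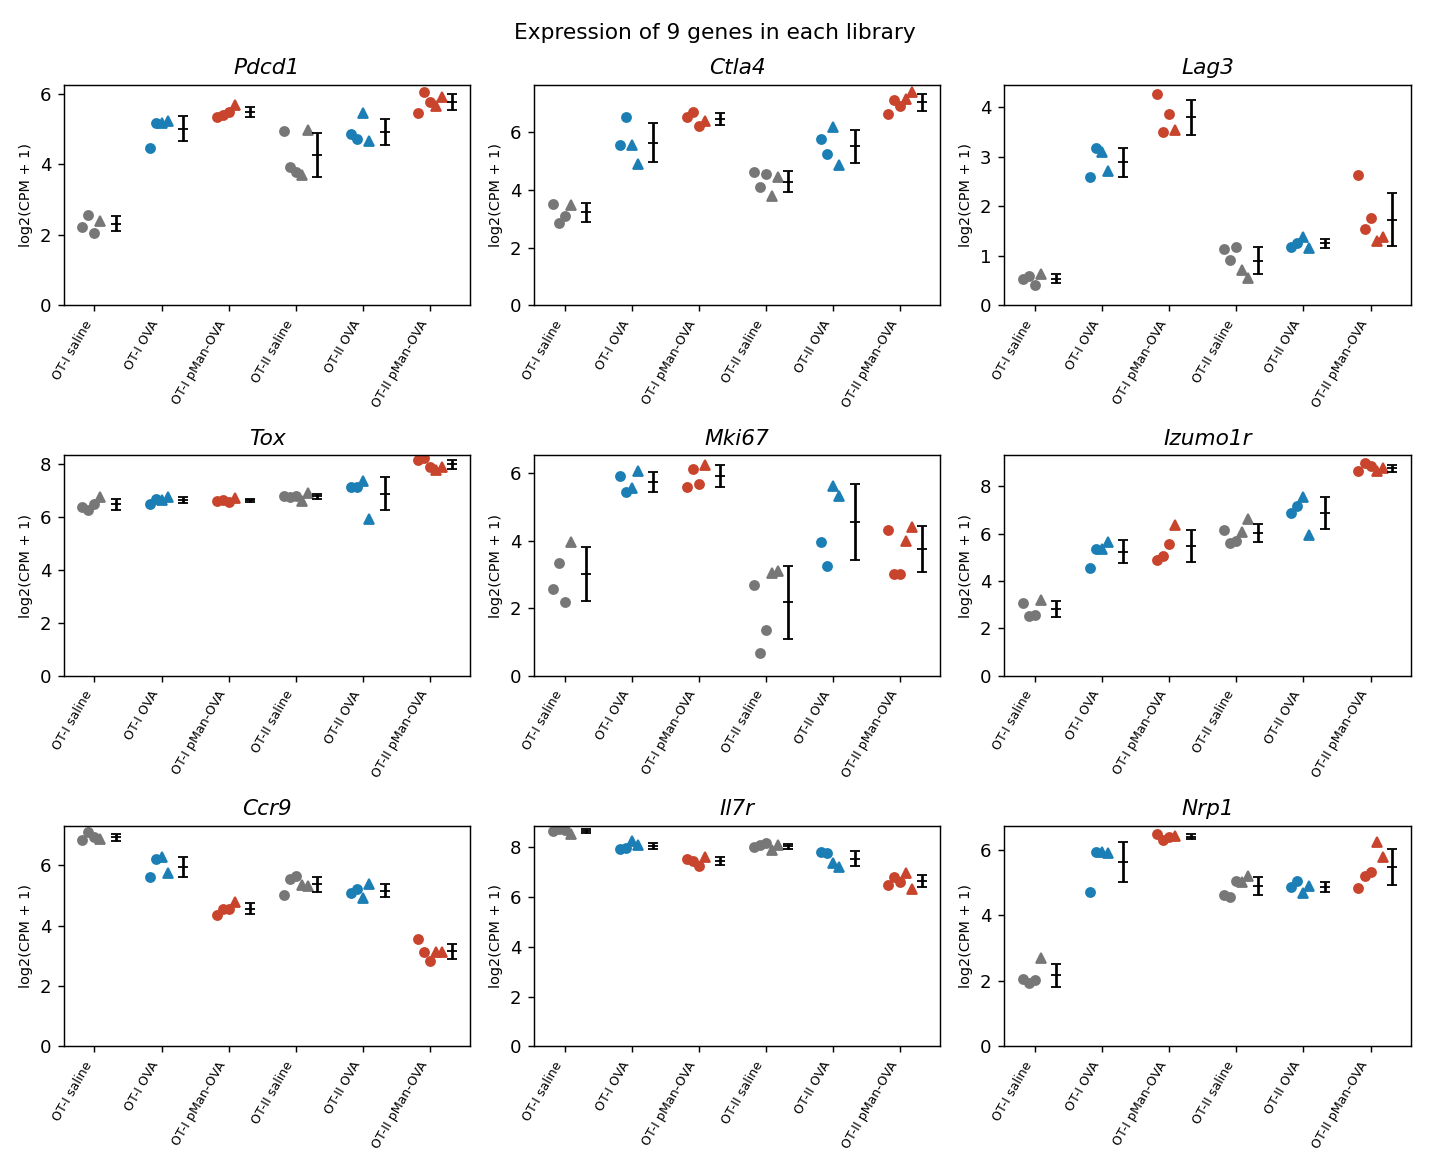
Expression of 9 genes as log2(CPM + 1) in each library by cell type and treatment, with circles for batch 1, triangles for batch 2 and black marks for the mean ± SD of 4 or 5 libraries. Pdcd1 in OT-I cells averages 3.99, 31.9 and 43.7 CPM with saline, OVA and pMan-OVA, and Izumo1r in OT-II cells 66.6, 126 and 438.

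The changes of both treatments in OT-I cells went together. Of the 900 genes called with OVA, 900 had the same sign with pMan-OVA and 739 had a larger change with it. Among the genes called in both comparisons 664 were higher and 201 lower, against 70.1 and 17.3 for independent lists. Both comparisons use the same saline libraries. The covariance of their log2 fold changes across genes was 0.37, against 0.103 in simulations of unchanged groups that share drawn controls, a difference of 0.267. With the saline libraries split so that each comparison had its own, it averaged 0.268 (0.248 to 0.283 over 6 splits). The correlation was 0.713 (0.475 in the simulations) and the share of genes with the same sign 78.3% (65.9%). These are values across genes, which are not independent replicates.

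The direct comparison of pMan-OVA with OVA in OT-I cells asked what mannosylation adds. The named genes that passed were lower with pMan-OVA. Ccr9 had 62.2 ± 14.1 CPM with OVA and 22.7 ± 3.02 with pMan-OVA (SD, n = 4 each), a log2 fold change of -1.43 ± 0.15 (edgeR adjusted p = 0.00379; -1.46 in batch 1 and -1.25 in batch 2). Ggt1, a gamma-glutamyl transferase (-1.13 ± 0.15, adjusted p = 0.0135), Igfbp4 (-1.31 ± 0.20, adjusted p = 0.0338), Cnn3, a calponin (-1.18 ± 0.18, adjusted p = 0.0338), and Tle1, a transcriptional corepressor (-0.97 ± 0.15, adjusted p = 0.0338), were lower too. For these genes the 4 libraries per group did not overlap (2.86% by chance for unchosen genes). The sixth gene called was Aqp9. Pdcd1 lay at 0.52 ± 0.16 (adjusted p = 0.36), Lag3 at 1.00 ± 0.26 (adjusted p = 0.235), Ctla4 at 0.69 ± 0.27 (adjusted p = 0.496), Tox at 0.04 (adjusted p = 0.943) and Il7r at -0.56 ± 0.10 (adjusted p = 0.0652). Further always-named genes were Gzmb at -0.23 ± 0.47 (adjusted p = 0.923), Ifng at 0.70 ± 0.30 (adjusted p = 0.54), Il2ra at -0.76 (adjusted p = 0.704), Tcf7 at 0.16 (adjusted p = 0.65) and Mki67 at 0.29 ± 0.28 (adjusted p = 0.799).

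As lists, anergy genes (camera adjusted p = 0.000687, but adjusted p = 0.126 with an estimated correlation), inhibitory receptor and exhaustion genes (0.00243, but adjusted p = 0.0971 with an estimated correlation) and T follicular helper genes (0.000836, but adjusted p = 0.0631 with an estimated correlation) were shifted up with pMan-OVA. When adjusted over the list alone, 4, 3 and 3 members were higher. Naive and memory genes were shifted down (camera adjusted p = 0.0146, but adjusted p = 0.212 with an estimated correlation). When adjusted over the list alone, 6 of them were lower and 2 higher. Markers of B cells (camera adjusted p = 0.0237, but adjusted p = 0.82 with an estimated correlation), dendritic cells (0.00735, but adjusted p = 0.494 with an estimated correlation) and NK cells (0.0309, but adjusted p = 0.475 with an estimated correlation) were also shifted down with pMan-OVA. Without the 4 libraries with the highest B cell marker levels, the dendritic cell list had an adjusted p of 0.189 and the NK cell list 0.305, and the B cell list turned to the opposite direction (adjusted p = 0.669). G2 and M phase genes were shifted up (0.000194, but adjusted p = 0.651 with an estimated correlation), as were type I interferon genes (0.00508, but adjusted p = 0.8 with an estimated correlation). S phase genes (0.0129, but adjusted p = 0.813 with an estimated correlation) were shifted down. So were oxidative phosphorylation genes (0.044, but adjusted p = 0.818 with an estimated correlation) and chemokine receptor and homing genes (0.0436, but adjusted p = 0.212 with an estimated correlation). Oxidative phosphorylation had an adjusted p of 0.102 without the 4 libraries.

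In all, 6 of 13724 genes passed, each lower with pMan-OVA; 1172 had an unadjusted p under 0.05, and DESeq2 called 144 and limma voom 16. Without the filter 11 passed, with thinned counts 14, without a batch term 2, and with the B cell covariate or one fit of all libraries 3. Batch 1 libraries alone gave 1 gene, and batch 2 alone gave 0 by edgeR, with 254 at an unadjusted p under 0.05. Of the named calls, that of Ccr9 held in each of the 12 fits that leave out 1 library. Ggt1 no longer passed without OVA b1r2 (adjusted p = 0.0572), OVA b1r3 (0.123), pMan-OVA b1r1 (0.0508), pMan-OVA b1r3 (0.0681) or pMan-OVA b2r2 (0.0612). Igfbp4 passed only without OVA b2r2, Cnn3 without that library or pMan-OVA b1r2, and Tle1 without that library or OVA b1r2, with adjusted p up to 0.203 in the others. The count was as low as 1 without OVA b1r3, pMan-OVA b1r1 or pMan-OVA b1r3.

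**Figure D3:**
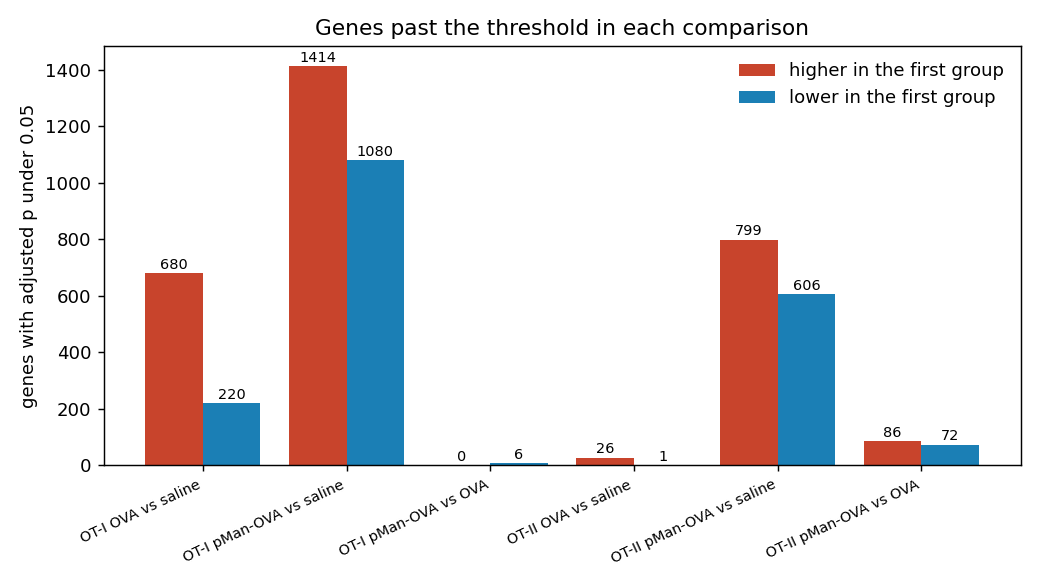
Number of genes with an adjusted p under 0.05 in each of the 6 comparisons, higher (red) and lower (blue) in the group named first. The bars run from 0 genes higher and 6 lower for OT-I pMan-OVA against OVA to 1414 and 1080 for OT-I pMan-OVA against saline.

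OT-II cells given free OVA were compared with saline to ask what the antigen alone does to CD4 T cells. Il2rb, P2rx7 and Itgb1 were among the genes that rose. Il2rb (ENSMUSG00000068227, chromosome 15, 78479256 to 78495271, minus strand), the interleukin 2 receptor beta chain, went from 86.5 ± 15.1 (SD, n = 5) to 247 ± 116 CPM (SD, n = 4), a log2 fold change of 1.41 ± 0.20 (edgeR adjusted p = 0.012; 0.98 in batch 1 and 1.82 in batch 2). P2rx7, an ATP-gated channel, went from 14.6 ± 2.57 (SD, n = 5) to 42 ± 13 CPM (SD, n = 4; 1.52 ± 0.21, adjusted p = 0.0105; 1.48 and 1.44). Itgb1 went from 156 ± 16.9 (SD, n = 5) to 271 ± 40.8 CPM (SD, n = 4; 0.78 ± 0.11, adjusted p = 0.0105; 0.66 and 0.91), and its adjusted p was 0.0522 without the 4 libraries with high B cell marker levels. These 3 calls held in each of the 14 fits that leave out 1 library.

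The largest rises by the naming rule included Ccnb2, a mitotic cyclin (2.96 ± 0.53, adjusted p = 0.0358), Cxcr5 (2.90 ± 0.49, adjusted p = 0.0307) and Wnt10a, a Wnt ligand (2.89 ± 0.42, adjusted p = 0.0126). The others were Eomes (2.07 ± 0.33, adjusted p = 0.0202), Chst2, a sulfotransferase (1.98 ± 0.29, adjusted p = 0.0128), and Cd86, a ligand of CD28 that B cells and other antigen-presenting cells carry (1.93 ± 0.30, adjusted p = 0.0161). Epc1 fell (-0.56 ± 0.10, adjusted p = 0.0345). Without saline b1r2, Wnt10a, Chst2 and Cd200 (1.31 ± 0.20, adjusted p = 0.0149) no longer passed (0.0553 each). Eomes no longer passed without saline b1r2 (0.0728), b1r3 (0.0733) or b2r2 (0.0776), nor Cd86 without saline b1r2 (0.0636), b1r3 (0.0573) or b2r2 (0.0648). Cxcr5 no longer passed without pMan-OVA b1r2 (0.0652) or saline b1r1 (0.0546), b1r2 (0.0886), b1r3 (0.105) or b2r2 (0.106). Ccnb2 passed in 4 of the 14 fits (without pMan-OVA b1r2, pMan-OVA b1r1, saline b1r1 or OVA b2r2; adjusted p up to 0.146 in the others). Epc1 passed in 3 (without pMan-OVA b1r2, pMan-OVA b1r1 or OVA b1r2; up to 0.131). Without the 4 libraries their adjusted p was 0.184 and 0.24.

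As lists, G2 and M phase genes had 2 of 22 higher and 12 when adjusted over the list alone (camera adjusted p = 1.77e-28, and adjusted p = 0.03 with an estimated correlation). T follicular helper genes had 3 of 17 higher, and 8 higher and 1 lower when adjusted over the list alone (2.01e-09, and adjusted p = 0.00816 with an estimated correlation). Inhibitory receptor and exhaustion genes had 2 of 20 higher, and 5 when adjusted over the list alone (8.88e-08, and adjusted p = 0.0225 with an estimated correlation). Regulatory type 1 genes had 1 of 11 higher, and 2 when adjusted over the list alone (0.000285, and adjusted p = 0.0244 with an estimated correlation). Anergy genes had 3 of 16 higher when adjusted over the list alone (camera adjusted p = 0.00493, but adjusted p = 0.05 with an estimated correlation), and S phase genes 7 of 22 (1.65e-08, but adjusted p = 0.137 with an estimated correlation). Activation genes had 6 of 20 higher when adjusted over the list alone (0.000575, but adjusted p = 0.198 with an estimated correlation) and regulatory T cell genes 5 of 16 (0.000285, but adjusted p = 0.107 with an estimated correlation). T helper 1 genes had 5 of 14 higher when adjusted over the list alone (2.3e-05, but adjusted p = 0.196 with an estimated correlation). Immediate early and stress genes were shifted down (1.25e-07, but adjusted p = 0.31 with an estimated correlation).

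The OVA group in these comparisons holds OT-II OVA b2r2, in which markers of B cells and NK cells were high. B cell markers were shifted up with OVA (median log2 fold change 1.79; camera adjusted p = 0.0306, but adjusted p = 0.807 with an estimated correlation). They turned to the opposite direction without the 4 libraries with high B cell marker levels (adjusted p = 0.744) and with batch 1 alone (0.0607). NK cell markers were shifted up (median 1.44; 0.00465, but adjusted p = 0.634 with an estimated correlation; 0.775 without the 4 libraries). Cytotoxic genes had a median of 0.95 (camera adjusted p = 0.132), and Gzmb, at 34.5 CPM in OT-II OVA b2r2 and 0.814 to 2.39 in the other OVA libraries, had a log2 fold change of 1.58 ± 1.08 (adjusted p = 0.808). Chemokine receptor and homing genes were shifted up (0.024, but adjusted p = 0.355 with an estimated correlation) and naive and memory genes down (0.00217, but adjusted p = 0.212 with an estimated correlation). Interferon gamma genes were shifted down (0.00304, but adjusted p = 0.282 with an estimated correlation) and apoptosis genes up (0.0395, but adjusted p = 0.141 with an estimated correlation). These 4 calls were lost without the 4 libraries, with an adjusted p of 0.117 for chemokine receptor and homing genes, 0.125 for interferon gamma genes and 0.0978 for naive and memory genes and for apoptosis genes. Ribosomal protein genes were shifted down (0.022, but adjusted p = 0.815 with an estimated correlation).

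Of the genes always named, Pdcd1 lay at 0.58 ± 0.29 (adjusted p = 0.708), Tox at 0.22 ± 0.20 (0.874) and Il7r at -0.49 ± 0.14 (0.319). Ctla4 lay at 1.31 ± 0.26 (adjusted p = 0.0619; it passed without OVA b2r2, at 1.49 and 0.0116) and Mki67 at 2.42 ± 0.52 (adjusted p = 0.0812; it passed without saline b1r1, at 2.88 and 0.0285). Lag3 lay at 0.82 ± 0.44 (0.731), Tcf7 at -0.22 ± 0.25 (0.899), Il2ra at 0.79 ± 0.21 (0.232), Foxp3, the master factor of regulatory T cells, at 0.28 ± 0.25 (0.866) and Tbx21 at 1.54 ± 0.39 (0.222). Without OVA b2r2, Tbx21 lay at 0.86 (0.396), Tcf7 at 0.06 and Foxp3 at 0.04 (both 1). Ifng lay at 0.61 ± 0.55 (0.866), Bcl6, the master factor of follicular helper cells, at 0.40 ± 0.28 (0.818), and Il21 at -0.04 ± 1.27 (0.998).

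In all, 27 of 14125 genes passed, 26 higher and 1 lower with OVA; 1058 had an unadjusted p under 0.05, and DESeq2 called 163, limma voom 147, one fit of all libraries 120 and the B cell covariate fit 47. Batch 1 libraries alone gave 5 genes, and batch 2 alone gave 0 by edgeR, with 1215 at an unadjusted p under 0.05. The OVA and saline libraries did not overlap in the 13 named genes that passed (1.59% by chance for unchosen genes). The count was as low as 8 without saline b1r2.

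OT-II cells given pMan-OVA were compared with saline to ask what the mannosylated antigen does to CD4 T cells. Ctla4, Izumo1r, Cd200, Tox and Pdcd1 rose, and Il7r and Ccr9 fell. Ctla4 (ENSMUSG00000026011, chromosome 1, 60887000 to 60915832, plus strand) went from 19 ± 4.55 to 132 ± 26.3 CPM (SD, n = 5 each), a log2 fold change of 2.79 ± 0.26 (edgeR adjusted p = 2.29e-05; 2.51 in batch 1 and 3.25 in batch 2). Izumo1r (ENSMUSG00000031933, chromosome 9, 14885814 to 14903949, minus strand) went from 66.6 ± 19.6 to 438 ± 44.9 CPM (SD, n = 5 each; 2.73 ± 0.26, adjusted p = 3.16e-05). Cd200 (ENSMUSG00000022661, chromosome 16, 45382135 to 45409053, minus strand), whose product restrains myeloid cells, went from 22.1 ± 6.07 to 152 ± 14 (SD, n = 5 each; 2.78 ± 0.20, adjusted p = 3.51e-06). Tox (ENSMUSG00000041272, chromosome 4, 6686353 to 6991557, minus strand) went from 109 ± 8.58 to 255 ± 32.9 CPM (SD, n = 5 each; 1.22 ± 0.19, adjusted p = 0.0012; 1.31 and 1.09 within the batches). Pdcd1 went from 19.8 ± 9.32 to 53.9 ± 8.61 (SD, n = 5 each; 1.45 ± 0.28, adjusted p = 0.00441; 1.59 and 1.5).

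By the naming rule the largest rises were those of Wnt10a (5.44 ± 0.45), Hdac9, a histone deacetylase (3.68 ± 0.68), Bmp7, a bone morphogenetic protein (3.46 ± 0.28), Endod1 (3.41 ± 0.24), Synpo, an actin-binding protein (3.27 ± 0.35), and Cxcr5 (3.25 ± 0.49). Bmp7 went from 5.87 ± 2.1 to 63.6 ± 7.37 CPM (SD, n = 5 each). The largest falls were those of Ly6c1 (-3.21 ± 0.33), Pdlim4 (-3.15 ± 0.42), Dntt, the terminal transferase of immature lymphocytes (-3.14 ± 0.34), Myo6, a myosin (-3.01 ± 0.39), Ampd1 (-2.47 ± 0.48) and Ccr9 (-2.36 ± 0.18). Adjusted p for these 12 genes lay between 3.51e-06 and 0.00509. Ly6c1 has a near-identical neighbour, Ly6c2, with which it may share reads.

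Inhibitory receptor and exhaustion genes had 8 of 20 higher (10 when adjusted over the list alone; camera adjusted p = 8.84e-08, and adjusted p = 0.0225 with an estimated correlation). Eomes rose by 3.04 ± 0.33 and Tox2 by 2.39 ± 0.34. Lag3 lay at 1.5 ± 0.41 (adjusted p = 0.0331) and passed in 5 of the 14 fits that leave out 1 library, those without OVA b1r2, OVA b1r3, OVA b2r1, OVA b2r2 or pMan-OVA b1r1 (adjusted p up to 0.0823 in the others). Anergy genes had 8 higher and 1 lower of 16 (9 and 1 when adjusted over the list alone; camera adjusted p = 1.25e-07, and adjusted p = 0.00672 with an estimated correlation). The calcium-dependent factor Nfatc1 (0.91 ± 0.10) and the ubiquitin ligase Cblb (0.91 ± 0.13) rose. T follicular helper genes had 9 of 17 higher (12 higher and 2 lower when adjusted over the list alone; camera adjusted p = 6.56e-12, and adjusted p = 0.00672 with an estimated correlation). They included Slamf6 (1.55 ± 0.15) and P2rx7 (2.41 ± 0.21). Regulatory T cell genes had 6 of 16 higher (8 when adjusted over the list alone; camera adjusted p = 1.29e-06, and adjusted p = 0.0365 with an estimated correlation). Among them were Ikzf2, which encodes Helios (2.5 ± 0.43), and Il2ra (0.95 ± 0.19). Foxp3 lay at 0.38 ± 0.24 (adjusted p = 0.376), with 19.3 CPM after saline and 25 after pMan-OVA. Regulatory type 1 genes had 5 higher and 1 lower of 11 (6 and 1 when adjusted over the list alone; camera adjusted p = 1.9e-05, and adjusted p = 0.0127 with an estimated correlation).

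Activation genes had 9 higher and 1 lower of 20 (10 and 3 when adjusted over the list alone; camera adjusted p = 1.29e-07, and adjusted p = 0.0499 with an estimated correlation). They included Il2rb (2.06 ± 0.19), Icos, a costimulatory receptor (1.44 ± 0.22), Tnfrsf9 (1.38 ± 0.19) and Cd44 (1.37 ± 0.13). Apoptosis genes had 6 higher and 1 lower of 20 (7 and 2 when adjusted over the list alone; camera adjusted p = 0.00328, and adjusted p = 0.0432 with an estimated correlation). G2 and M phase genes had 5 of 22 higher (6 when adjusted over the list alone; camera adjusted p = 3.21e-05, but adjusted p = 0.44 with an estimated correlation), with Top2a at 1.60 ± 0.29. Mki67 lay at 1.81 ± 0.49 (adjusted p = 0.0307) and no longer passed without pMan-OVA b1r2 (0.0606) or saline b1r3 (0.084), b2r1 (0.0594) or b2r2 (0.0515). Immediate early and stress genes had 8 of 20 lower (16 when adjusted over the list alone; camera adjusted p = 1.19e-09, but adjusted p = 0.222 with an estimated correlation). Ier2 lay at -1.23 ± 0.19 and Junb at -1.45 ± 0.30. Interferon gamma genes had 4 of 20 lower (5 when adjusted over the list alone; camera adjusted p = 0.00955, but adjusted p = 0.355 with an estimated correlation). The cytokine signalling suppressor Socs3 lay at -1.66 ± 0.24 and Irf1 at -0.66 ± 0.10. Cholesterol synthesis genes had 3 lower and 1 higher of 22 (7 and 1 when adjusted over the list alone; camera adjusted p = 0.00905, but adjusted p = 0.634 with an estimated correlation). T cell receptor signalling genes had 3 of 22 higher (4 higher and 1 lower when adjusted over the list alone; camera adjusted p = 0.0195, but adjusted p = 0.76 with an estimated correlation), the phosphatase Ptpn22 at 0.86 ± 0.11.

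Naive and memory genes moved both ways, with 5 lower, Il7r (-1.40 ± 0.14) and Igfbp4 (-1.79 ± 0.28) among them, and 4 higher of 20 (6 and 4 when adjusted over the list alone; camera adjusted p = 0.378). T helper 1 genes had 2 higher and 1 lower of 14 (3 and 2 when adjusted over the list alone; camera adjusted p = 0.488), with Il18r1, a chain of the interleukin 18 receptor, at -2.17 ± 0.18 and Stat4 at 0.89 ± 0.09. Tbx21 lay at -0.04 ± 0.36 (adjusted p = 0.966), Gzmb at 0.14 ± 0.88 (0.956), Ifng at 0.71 (0.422), Tcf7 at 0.20 ± 0.23 (0.68) and Il21 at -1.27 ± 1.52 (0.691). Bcl6 lay at 0.81 ± 0.27 (adjusted p = 0.0714), and passed without OVA b2r2 (0.79, adjusted p = 0.0386).

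In all, 1405 of 14125 genes passed, 799 higher and 606 lower with pMan-OVA; 3310 had an unadjusted p under 0.05, and DESeq2 called 2164, limma voom 2762, one fit of all libraries 2110 and the fit without a batch term 857. Batch 1 libraries alone gave 802 genes and batch 2 alone gave 6. The pMan-OVA and saline libraries did not overlap in 64 of the 77 named genes that passed (0.794% by chance for unchosen genes). Of the 27 genes called with OVA, 23 changed more with pMan-OVA, and 24 were called higher and 1 lower in both comparisons, against 1.47 and 0.0429 for independent lists. The covariance of the 2 sets of log2 fold changes, which share the saline libraries, was 0.321 (0.196 in simulations of unchanged groups), and 0.122 with the saline libraries split (0.0361 to 0.167 over 10 splits). The correlation was 0.556 (0.467 in the simulations) and the same-sign share 70.6% (65.8%), across genes that are not independent replicates.

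The direct comparison of pMan-OVA with OVA in OT-II cells asked what mannosylation adds in CD4 T cells. Izumo1r, Bmp7, Cd200 and Slamf6 were higher with pMan-OVA, and Ccr9, Il18r1 and Il7r were lower. Izumo1r had 126 ± 51.8 CPM with OVA (SD, n = 4) and 438 ± 44.9 with pMan-OVA (SD, n = 5), a log2 fold change of 1.81 ± 0.28 (edgeR adjusted p = 0.00729; 1.81 in batch 1 and 1.98 in batch 2). Bmp7 (ENSMUSG00000008999, chromosome 2, 172868012 to 172940321, minus strand) had 15.2 ± 4.95 (SD, n = 4) and 63.6 ± 7.37 CPM (SD, n = 5; 2.05 ± 0.28, adjusted p = 0.00469; 2.06 and 2.22). Cd200 had 56.5 ± 14.3 (SD, n = 4) and 152 ± 14 (SD, n = 5; 1.47 ± 0.20, adjusted p = 0.00469). Slamf6, a receptor of follicular helper and stem-like T cells, differed by 1.14 ± 0.16 (adjusted p = 0.00469). Ccr9 had 34.7 ± 5.05 (SD, n = 4) and 7.99 ± 1.64 CPM (SD, n = 5; -2.13 ± 0.18, adjusted p = 0.00016; -2.12 and -2.14). Il18r1 (-1.74 ± 0.19, adjusted p = 0.000704), Il7r (-0.92 ± 0.14, adjusted p = 0.00756), Dntt (-2.38 ± 0.35, adjusted p = 0.0056) and Ly6c1 (-2.20 ± 0.32, adjusted p = 0.00613) were lower too. The calls of these 9 genes held in each of the 14 fits that leave out 1 library.

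The largest rises by the naming rule were those of Wnt10a (2.55 ± 0.42, adjusted p = 0.013), Spry1, an inhibitor of receptor tyrosine kinase signalling (2.28 ± 0.38, 0.013), and Ppic, a cyclophilin (2.16 ± 0.41, 0.0229). Next came Synpo (2.05 ± 0.36, 0.0171), Bmp7 and Rundc3a (1.90 ± 0.34, 0.018). Without OVA b1r2, the adjusted p was 0.0779 for Wnt10a, 0.0682 for Spry1, 0.0875 for Synpo, 0.0804 for Rundc3a and 0.111 for Ppic. Rundc3a was also lost without OVA b1r3 (0.075), and Ppic without OVA b1r3 (0.0571), pMan-OVA b1r3 (0.0565) or pMan-OVA b2r1 (0.0589). The largest falls were those of Dntt, Ly6c1 and Ccr9, given above, and of Myo6 (-2.35 ± 0.39, 0.013), Pdlim4 (-2.19 ± 0.42, 0.0229) and Prf1, the pore-forming protein of cytotoxic cells (-1.79 ± 0.38, 0.0393). Myo6 was lost without OVA b1r2 (0.0535), and Pdlim4 without OVA b1r3 (0.075), OVA b1r2 (0.0954), pMan-OVA b1r3 (0.0638), b2r1 (0.0707) or b2r2 (0.0682). Prf1 passed in 3 of the 14 fits, those without saline b2r2, OVA b2r1 or OVA b2r2 (adjusted p up to 0.135 in the others), and its log2 fold change was -1.07 without OVA b2r2, where cytotoxic and NK cell genes were high.

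Among the always-named genes, Ctla4 lay at 1.48 ± 0.26 (adjusted p = 0.0177; lost without OVA b1r3, 0.0571, or OVA b1r2, 0.0912). Tox lay at 1.01 ± 0.21 (adjusted p = 0.0327), and passed in 6 of the 14 fits, those without pMan-OVA b1r2, saline b1r1, saline b2r1, saline b2r2, OVA b2r1 or OVA b2r2 (adjusted p up to 0.113 in the others). Pdcd1 lay at 0.87 ± 0.30 (0.203), Lag3 at 0.67 ± 0.44 (0.583), Foxp3 at 0.10 (0.922), Cxcr5 at 0.35 ± 0.50 (0.841), Bcl6 at 0.41 (0.619) and Il21 at -1.23 (0.785). Mki67 lay at -0.61 ± 0.51 (0.689), Tcf7 at 0.42 ± 0.25 (0.53), Il2ra at 0.16 (0.822), Ifng at 0.10 (0.969) and Gzmb at -1.45 ± 1.11 (0.656). Tbx21 lay at -1.58 ± 0.39 (adjusted p = 0.0703), passed without OVA b2r1 (-1.79, 0.0347), and lay at -0.89 without OVA b2r2 (0.124), the OVA library with 73.7 CPM against 16.1 to 17.2 in the others. Without it Tcf7 lay at 0.14 (0.606) and Foxp3 at 0.34 (0.687).

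As lists, anergy genes had 2 of 16 higher, and 7 higher and 1 lower when adjusted over the list alone (camera adjusted p = 1.36e-06, and adjusted p = 0.00766 with an estimated correlation). T follicular helper genes had 2 of 17 higher, and 5 when adjusted over the list alone (7.8e-06, and adjusted p = 0.0275 with an estimated correlation). Regulatory type 1 genes had 2 of 11 higher, and 4 higher and 1 lower when adjusted over the list alone (0.00355, and adjusted p = 0.0499 with an estimated correlation; median 0.36, mean -0.03). Inhibitory receptor and exhaustion genes had 3 of 20 higher, over all genes and adjusted over the list alone (0.00231, but adjusted p = 0.168 with an estimated correlation; median 0.16, mean -0.02, test upward). Regulatory T cell genes had 2 of 16 higher, and 3 when adjusted over the list alone (0.000274, but adjusted p = 0.111 with an estimated correlation). Activation genes had 1 of 20 higher, and 5 higher and 1 lower when adjusted over the list alone (2.02e-05, but adjusted p = 0.111 with an estimated correlation). T cell receptor signalling and apoptosis genes were shifted up (3.18e-06 and 0.0241, but adjusted p = 0.355 and 0.111 with an estimated correlation). In OT-II OVA b2r2, 15 of 22 T cell receptor signalling genes were lower than in each other OT-II library, which may add to their shift. S phase, G2 and M phase, immediate early and cholesterol synthesis genes were shifted down (2.5e-05, 0.000844, 9.55e-05 and 0.00327). With an estimated correlation their adjusted p was 0.295, 0.616, 0.496 and 0.581. When adjusted over the list alone, 6 S phase and 4 cholesterol synthesis genes were lower.

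Markers of macrophages (median -1.62), dendritic cells (-1.71) and neutrophils (-1.85) were shifted down with pMan-OVA (camera adjusted p = 0.00235, 0.00026 and 0.00353, but adjusted p = 0.708, 0.473 and 0.634 with an estimated correlation). Without the 4 libraries with high B cell marker levels the macrophage and dendritic cell values were 0.171 and 0.146. B cell markers had a median of -1.52 (camera adjusted p = 0.284) and the opposite direction with batch 1 alone (0.00819). Cytotoxic genes (median -1.24; 0.00688, but adjusted p = 0.655 with an estimated correlation) and T helper 1 genes (median -0.72; 0.0124, but adjusted p = 0.496 with an estimated correlation) were shifted down beside them, and had adjusted p of 0.34 and 0.619 without the 4 libraries. Type I interferon genes (0.00976, but adjusted p = 0.581 with an estimated correlation) and CD4 lineage genes (0.015, but adjusted p = 0.349 with an estimated correlation) were shifted up. Chemokine receptor and homing genes (0.00514, but adjusted p = 0.236 with an estimated correlation) and unfolded protein response genes (0.0241, but adjusted p = 0.451 with an estimated correlation) were shifted down. Without the 4 libraries these lists had 0.199, 0.67, 0.0978 and 0.219.

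In all, 158 of 14125 genes passed, 86 higher and 72 lower with pMan-OVA; 1800 had an unadjusted p under 0.05, and DESeq2 called 634, limma voom 746, one fit of all libraries 495, the B cell covariate fit 287 and the fit without a batch term 66. Batch 1 libraries alone gave 71 genes, and batch 2 alone gave 0 by edgeR, with 920 at an unadjusted p under 0.05. The groups did not overlap in 23 of the 25 named genes that passed (1.59% by chance for unchosen genes). The count was as low as 29 without OVA b1r2.

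**Figure D4:**
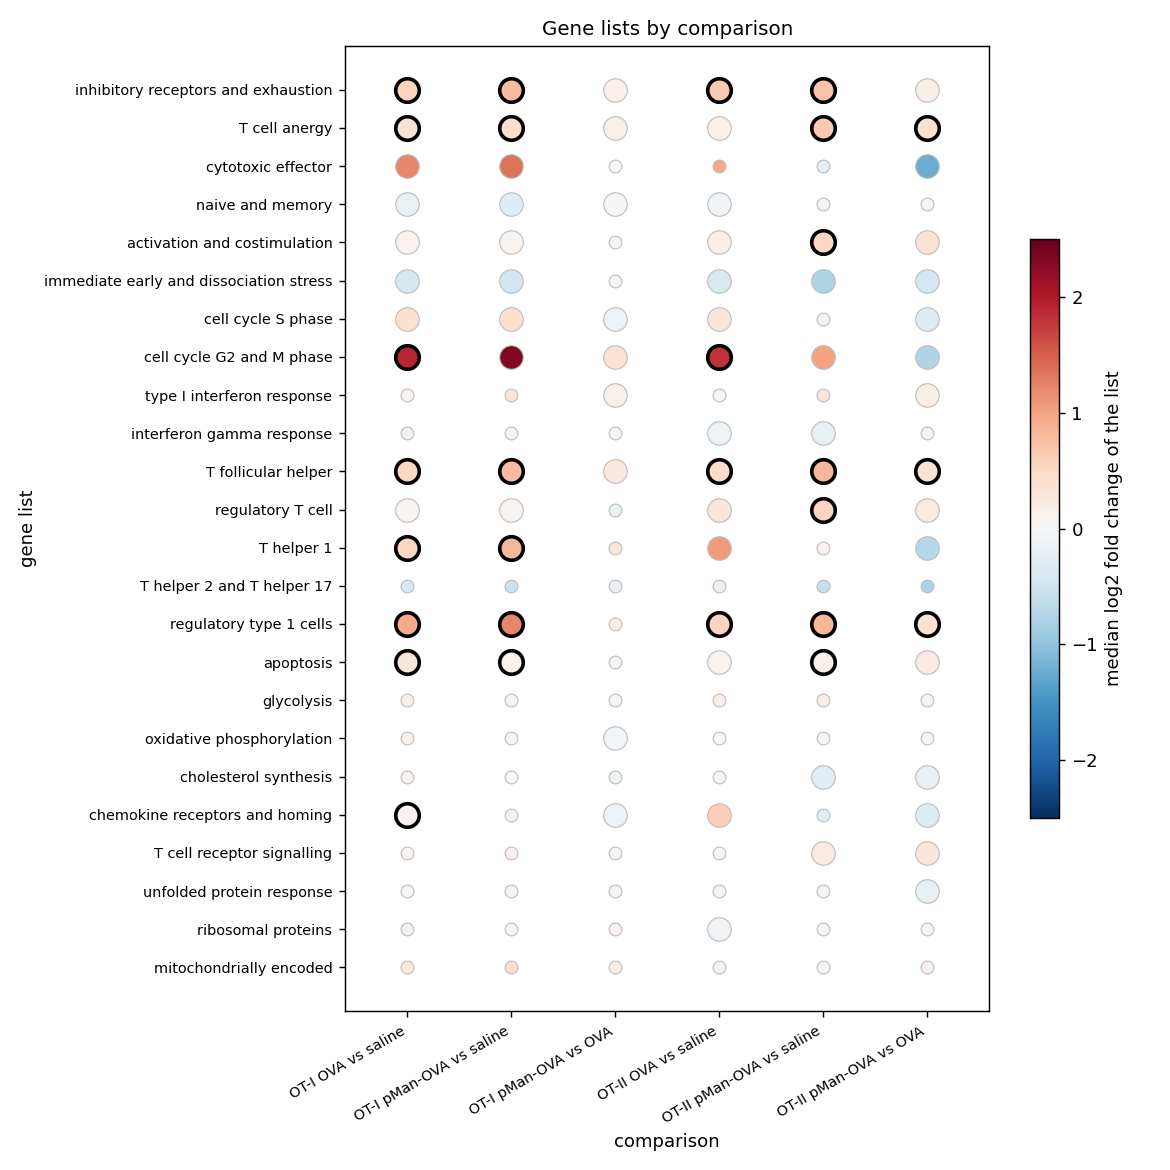
Median log2 fold change of 24 fixed gene lists (vertical axis) in the 6 comparisons (horizontal axis), given by colour, with large dots for a camera adjusted p under 0.05 and a thick black edge where the call holds with an estimated correlation. Median values for G2 and M phase genes in OT-I cells are 1.91 with OVA and 2.32 with pMan-OVA.

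Whether the cell types answered differently was tested as the difference between the OT-II and OT-I log2 fold changes in one model of the 26 libraries. With OVA, Nrp1 rose by 3.71 ± 0.26 in OT-I cells and lay at -0.04 ± 0.22 in OT-II cells, a difference of -3.75 ± 0.33 (edgeR adjusted p = 6.61e-07). Itgb1 lay at 3.18 ± 0.15 and 0.77 ± 0.13 (-2.41 ± 0.19, adjusted p = 2.23e-07). Pdcd1 lay at 2.90 ± 0.29 and 0.57 ± 0.25 (-2.33 ± 0.38, adjusted p = 0.00849; 0.064 without OT-I OVA b1r3). Tmem154 lay at 1.33 ± 0.17 and -0.03 ± 0.16 (-1.36 ± 0.23, adjusted p = 0.0141; lost without OT-I saline b1r1, 0.0535, or OT-I OVA b1r3, 0.064). Zbtb32 differed by -3.96 ± 0.74 (adjusted p = 0.0414). It passed in 6 of the 26 fits that leave out 1 library, those without OT-I saline b2r2, OT-II saline b1r2, OT-II saline b2r2, OT-II OVA b2r2, OT-II pMan-OVA b1r1 or OT-II pMan-OVA b2r2 (adjusted p up to 0.154 in the others). In all, 8 of 14722 genes passed, each with a lower value in OT-II cells, against 70 by DESeq2, 18 without the 4 libraries and 14 with batch 1 alone. The count was 3 without OT-I OVA b1r3, 5 without OT-I saline b1r1 and 24 without OT-II OVA b2r2.

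With pMan-OVA against saline, Sema4f and Sox4 moved in opposite directions. Sema4f, a semaphorin, had a log2 fold change of -1.68 ± 0.22 in OT-I and 0.99 ± 0.19 in OT-II cells (difference 2.67 ± 0.29, adjusted p = 1.63e-05). Sox4, a transcription factor, had -1.11 ± 0.28 and 1.26 ± 0.24 (2.37 ± 0.37, adjusted p = 0.000876). Ppic lay at -0.71 ± 0.35 and 2.75 ± 0.33 (3.46 ± 0.48, adjusted p = 0.000261). Cpq lay at 0.26 ± 0.31 and 2.5 ± 0.30 (2.24 ± 0.42, adjusted p = 0.00715). S100a4 lay at 3.93 ± 0.46 and -0.79 ± 0.37 (-4.73 ± 0.58, adjusted p = 6.66e-05), Zbtb32 at 5.65 ± 0.61 and 0.86 ± 0.47 (-4.79 ± 0.72, adjusted p = 0.000657), Gzmk at 4.74 ± 0.78 and 0.1 ± 0.6 (-4.64 ± 0.96, adjusted p = 0.013) and Nrp1 at 4.56 ± 0.27 and 0.66 ± 0.2 (-3.90 ± 0.32, adjusted p = 1.44e-07). Cxcr6 differed by 2.59 ± 0.59 (adjusted p = 0.025; lost without OT-I saline b1r1, 0.0522, OT-I saline b1r3, 0.0602, OT-I pMan-OVA b1r1, 0.071, OT-I pMan-OVA b1r3, 0.0671, or OT-II pMan-OVA b1r1, 0.0534). Dock5 differed by -3.36 ± 0.76 (adjusted p = 0.0224; lost without OT-I saline b1r1, 0.0654, OT-I saline b1r3, 0.0602, OT-I pMan-OVA b1r1, 0.0577, or OT-I pMan-OVA b1r3, 0.0518). In all, 260 genes passed, 140 with a higher and 120 with a lower value in OT-II cells, against 565 by DESeq2, 410 without the 4 libraries and 116 without a batch term. The count was as low as 130 without OT-I saline b1r3 and as high as 455 without OT-II OVA b2r2.

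With pMan-OVA against OVA, 7 genes passed, 6 with a higher and 1 with a lower value in OT-II cells, against 79 by DESeq2, 11 without the 4 libraries, 3 with thinned counts and 0 by edgeR without a batch term (917 unadjusted). The named ones were Ppic (2.75 ± 0.49, adjusted p = 0.0392), Sema4f (1.62 ± 0.30, 0.045), Cyth3 (1.06 ± 0.19, 0.0392), Hpcal1 (0.96 ± 0.16, 0.0392), Dusp6, a phosphatase of MAP kinases (0.88 ± 0.17, 0.0455), and Il18r1 (-1.49 ± 0.25, 0.0392). Each of these calls was lost in at least 15 of the 26 fits that leave out 1 library (adjusted p up to 0.258). In 12 of those fits edgeR called 0 genes, with 914 to 1211 at an unadjusted p under 0.05. The highest count was 23, without OT-II OVA b2r1. The differences for Tox (1.00 ± 0.25, adjusted p = 0.216) and Izumo1r (1.40 ± 0.38, adjusted p = 0.315), which passed in OT-II cells, did not pass, so these genes are not shown to respond differently to mannosylation in the 2 cell types.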

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

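The tests for RNA of other cells and for a swap in OT-II OVA b2r2, those with 4 libraries left out, thinned counts and the cell type difference for the number of pMan-OVA against OVA calls, and the count of splits for OT-I OVA against saline were chosen only after the result was seen. In 145 groups of 4 or 5 libraries, 22 had a library whose gap to the nearest other was large against the range of its group. Chance gives such a gap in about 1 of 20 groups.

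OT-II OVA b2r2 accounts for 8 of these. Its median marker level was 9.22 log2 CPM for B cells (2.13 to 3.3 in the other OT-II OVA libraries), 5.42 for dendritic cells (1.62 to 2.15), 5.02 for NK cells (0.05 to 0.38) and 4.94 for neutrophils (1.08 to 1.46). Gzmb was at 34.5 CPM (0.814 to 2.39), Tbx21 at 73.7 (16.1 to 17.2), Foxp3 at 38.4 (18.5 to 21) and Tcf7 at 756 (2420 to 2720).

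A candidate explanation for the pattern in OT-II OVA b2r2 is RNA of B cells and other blood cells, which a sort for OT-II cells should remove. Of 15 B cell markers, 15 were higher in it than in each other OT-II library (Cd74 at 14600 CPM), and Cd3e was lower. The B cell markers raised the flag, so they do not test that source. The library's 248 CPM of Cd4 argue against a full swap with an OT-I library (7.11 at most). Cd8a at 118 CPM (21.8 at most in other OT-II) leaves RNA of CD8 T cells open. Of 15 erythroid markers 3 were highest there, so amounts differed by cell type. No biological explanation was tested, and whether the cells entered at the sort or later stays open.

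More genes were called for pMan-OVA against OVA in OT-II cells (158) than in OT-I cells (6). RNA of other cells in 4 libraries is argued against as the whole cause, since OT-II cells gave 135 genes without them and OT-I cells 9. So are fewer counts in the OT-I libraries, with 182 and 14 genes at one depth. Larger OT-II groups may add to the gap, with 30, 45, 82 and 86 genes at the OT-I group sizes. All exceed 9, the highest in OT-I fits without 1 library. A different response of the cell types may add to it: the test of the difference called 7 genes. This stays open, because fits without 1 library gave as few as 0 by edgeR, with 914 to 1211 genes at an unadjusted p under 0.05, against 7 in the full fit and 79 by DESeq2.

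Immediate early and stress genes had 17 calls of lower values after pMan-OVA than after saline, of 9 of 20 members in OT-I and 8 of 20 in OT-II cells, while both list calls were lost with an estimated correlation (adjusted p = 0.336 and adjusted p = 0.222). Lower depth of some libraries is argued against, with 19 calls at one depth, and RNA of other cells in 4 libraries as the whole cause, with 15 calls without them (10 in OT-I and 5 in OT-II cells). Handling of the pools could also move these genes, and would move OT-I and OT-II libraries of one pool together if equal numbers marked one pool, which the labels do not say. Across 12 such pairs the deviations had r = 0.41 (permutation p = 0.194) and rho = 0.5 (permutation p = 0.102), r = 0.47 without the 2 farthest, and r = 0.04 over 8 pairs in batch 1 (exact permutation p = 0.953; rho = 0.21, p = 0.619) and r = 0.9 over 4 pairs in batch 2 (exact permutation p = 0.125; rho = 0.8, p = 0.333). Handling and an effect of the treatment therefore cannot be told apart for these genes.

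Among the other library values, plasma cell markers were at 2.08 log2 CPM in OT-I saline b1r1 (0.51 to 0.61 in the rest of its group). In OT-I OVA b2r1 macrophage markers were at -1.29 (1.56 to 1.84) and erythroid markers at -3.89 (-0.77 to -0.28). Neutrophil markers were at -2.23 in OT-I pMan-OVA b1r1 (-0.29 to -0.02), erythroid markers at 1.88 in OT-II saline b1r1 (0.43 to 0.81), and hepatocyte markers at -1.44 in OT-II pMan-OVA b2r2 (-5.61 in the others). Pdcd1 was at 21.1 CPM in OT-I OVA b1r2 (34.8 to 36.4), Lag3 at 5.24 in OT-II pMan-OVA b1r2 (1.46 to 2.39) and Tcf7 at 1380 in OT-I OVA b2r2 (1670 to 1710). Il2ra was at 1 CPM in OT-I saline b2r2 (4.33 to 4.65) and at 8.08 in OT-I OVA b2r2 (2.57 to 2.97). Cxcr5 was at 37.3 CPM in OT-II saline b2r1 (5.38 to 11.2), and Il21 at 2.84 in OT-II saline b1r1 (0.0277 to 0.585) and 1.95 in OT-II pMan-OVA b2r2 (0 to 0.365).

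The response differed between the cell types by the test of the difference (OT-II minus OT-I, log2) for 8 genes with OVA against saline, including Zbtb32 (-3.96), Nrp1 (-3.75), Itgb1 (-2.41), Pdcd1 (-2.33) and Tmem154 (-1.36). It did for 260 genes with pMan-OVA against saline, including Ppic (3.46), Sema4f (2.67), Cxcr6 (2.59), Sox4 (2.37), Cpq (2.24), Zbtb32 (-4.79), S100a4 (-4.73), Gzmk (-4.64), Nrp1 (-3.90) and Dock5 (-3.36), and for 7 with pMan-OVA against OVA, including Ppic (2.75), Sema4f (1.62), Cyth3 (1.06), Hpcal1 (0.96), Dusp6 (0.88) and Il18r1 (-1.49). The reported limits of the single calls hold here too.

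Within a cell type, the real split gave the most genes among splits of the same libraries into groups of these sizes. In OT-I cells 1 of 35 splits, the real one, gave as many genes in each comparison (900, 2494 and 6, and at most 0, 0 and 1 by edgeR in the others). In OT-II cells 1 of 100 did (27, 1405 and 158, and at most 8, 1 and 13). For the difference between cell types, 4, 4 and 3 of 100 splits gave as many as 8, 260 and 7 genes, with 251, 2149 and 119 as the highest. Splits that mix treated and control libraries break up a treatment effect, also one shared by both cell types, and differ in batch make-up. They do not decide whether chance can be excluded for any of these counts.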

How the results depend on the processing

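The fits without 4 libraries with high B cell marker levels, with that level as a covariate and with thinned counts were chosen only after the result was seen. Counts of genes are given in the order OT-I OVA against saline, OT-I pMan-OVA against saline, OT-I pMan-OVA against OVA, then the same for OT-II cells, with the tests between cell types last, and the cause of a change was not tested unless given. No count moved by over 1.5 times with RLE size factors.

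DESeq2 gave 1430 genes for the first comparison, 144 for the third and 163, 2164 and 634 in OT-II cells, and 70, 565 and 79 between cell types. Voom gave 1677, 16, 147, 2762 and 746 in the first and the last 4 comparisons within a cell type. One fit of all libraries gave 391, 1618, 3, 120, 2110 and 495. Without a batch term the third comparison gave 2, OT-II pMan-OVA 857 against saline and 66 against OVA, and the last tests between cell types 116 and 0 by edgeR, with 917 at an unadjusted p under 0.05. No filter gave 11 in the third. A log2 fold change of at least 1 gave 369, 784, 468 and 61 in the comparisons it moved, since fewer genes can pass.

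Batch 1 alone, with fewer libraries, gave 1 in the third comparison, 5, 802 and 71 in OT-II cells and 14 for OVA between cell types. Batch 2 alone, with 1 or 2 libraries per group, gave 0, 2, 0, 0, 6 and 0 by edgeR, with 818, 254, 1215 and 920 genes at an unadjusted p under 0.05 where it gave 0; a lone library is assumed to vary like the others. The replicate block gave 0 in the third comparison (774 unadjusted), 96 for OT-II pMan-OVA against OVA and 5, 86 and 0 (991 unadjusted) between cell types. Whether equal replicate numbers pair samples stays open at these group sizes. Such pairs correlated above 0.1 in 2 of 10 OT-I, 3 of 13 OT-II and 5 of 12 cases across cell types.

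The B cell covariate gave 3 in the third comparison, and 47 and 287 for OT-II OVA against saline and pMan-OVA against OVA. Thinned counts gave 14 in the third and 3 in the last test between cell types, and the others stayed within 1.5 times. Without the 4 libraries the tests between cell types gave 18, 410 and 11. The covariance of the fold changes was 0.738 and 0.728 without the filter, which adds genes with few counts, and 0.268 and 0.122 with the saline libraries split, which removes the shared controls.

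Without 1 library each, the counts ran from 481 to 921, 1767 to 2770 and 1 to 9 in OT-I, 8 to 37, 992 to 1793 and 29 to 211 in OT-II, and 3 to 24, 130 to 455 and 0 to 23 between cell types. The covariance ran from 0.366 to 0.46 in OT-I and from 0.281 to 0.447 in OT-II cells.

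Some lists turned direction. With batch 1 alone these were mitochondrially encoded genes in OT-I OVA against saline (down, adjusted p = 0.00731), T cell receptor signalling genes (up, 0.0378) and B cell markers (down, 0.0607) in OT-II OVA against saline, and B cell markers in OT-II pMan-OVA against OVA (up, 0.00819). Without the 4 libraries they were B cell markers in OT-I pMan-OVA against OVA (up, 0.669) and in OT-II OVA against saline (down, 0.744). No named call (0) turned direction. Of 287 named calls, 287 held with DESeq2, 285 with RLE, 282 with thinned counts, 275 without the filter, 265 without the 4 libraries, 246 with the replicate block, 232 without a batch term and 228 with batch 1 alone. Of 266 within a cell type, 265 held with voom, 263 with the B cell covariate, 223 with one fit of all libraries and 3 with batch 2 alone. List calls in the same direction were lost in 63 tests with an estimated correlation, 38 with fry, which does not compare a list with other genes, 21 with batch 1 alone, 16 without the 4 libraries and 4 with the replicate block.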

Other observations

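Glycolysis genes had 4 of 18 higher in OT-I cells with OVA (5 higher and 1 lower when adjusted over the list alone; camera adjusted p = 0.0876) and 6 higher and 3 lower with pMan-OVA (camera adjusted p = 0.408), the phosphofructokinase Pfkp at 0.64 ± 0.12 and 0.85 ± 0.11. In OT-II cells with pMan-OVA 2 rose and 2 fell (camera adjusted p = 0.28), with Pfkp at 0.64 ± 0.12 and the glucose transporter Slc2a1 at -0.55 ± 0.13. Cholesterol synthesis genes had 3 higher and 2 lower of 22 in OT-I cells with pMan-OVA (camera adjusted p = 0.924). Unfolded protein response genes had 2 lower, with the stress factor Atf4 at -0.79 ± 0.10 and Trib3 at -1.83 ± 0.37, and 1 higher, Pdia3 at 0.37 ± 0.09, in OT-II cells with pMan-OVA (camera adjusted p = 0.126; Pdia3 0.0522 without the 4 libraries with high B cell marker levels). Oxidative phosphorylation, ribosomal protein and mitochondrially encoded genes had camera adjusted p of 0.966, 0.384 and 0.966 there, and 0.918, 0.566 and 0.389 in OT-I cells.

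Interferon genes moved both ways with pMan-OVA. Type I interferon genes had 5 higher and 2 lower of 23 in OT-I cells (camera adjusted p = 0.208) and 5 higher and 3 lower in OT-II cells (camera adjusted p = 0.0557), where the antiviral sensor gene Oas1a rose by 1.10 ± 0.12 and Bst2 lay at -0.52 ± 0.11. Interferon gamma genes in OT-I cells had 4 higher and 5 lower of 20 (median -0.07, mean 0.20; camera adjusted p = 0.581), Irf8 at 1.28 ± 0.20 and Gbp2 at -0.63 ± 0.09. T helper 2 and 17 genes had 1 higher, Gata3 at 0.46 ± 0.10, and 2 lower of 9, Il23r at -2.48 ± 0.62 among them, in OT-I cells with pMan-OVA (camera adjusted p = 0.379).

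In OT-I cells with pMan-OVA, markers of plasma cells, erythroid cells, hepatocytes and stroma had camera adjusted p of 0.5, 0.885, 0.956 and 0.553, and in OT-II cells 0.81, 0.284, 0.313 and 0.605. CD4 lineage genes in OT-I cells had 2 higher, Zbtb7b at 1.75 ± 0.38 among them, and 1 lower of 8 (camera adjusted p = 0.635).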
